A study of Rorippa amphibia and Rorippa sylvestris and Rorippa anceps with 20 samples.

How the data were processed

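Root RNA was measured for R. amphibia, R. sylvestris and an F1 hybrid between these Rorippa species on Affymetrix ATH1 arrays, whose probes were designed for Arabidopsis thaliana. The 18 RNA arrays fell into 6 groups of 3, with each genotype either kept in air or completely under water for 24 h. Per the labels, the parental plants were clones from a rhizome of each species, and each array held a pool of 3 plants, so that a species difference here is a difference between the clones used. Another 2 arrays, 1 per species, carried genomic DNA. Arrays were assigned to groups by their titles, and no column of the table was left unused.

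The table deposited by the authors holds an intensity per probe set. The RNA intensity values were made with RMA, per the submitters' processing notes, and, per the labels, after probes with a genomic DNA hybridisation intensity below a threshold of 80 had been masked. The version of RMA is not given in the sources used here. The values proved to be on a linear scale (lowest value 4.51), whereas log2 values had been assumed when the tests were chosen, so that log2 was taken here with a floor of 1 that no value reached. All 18 RNA columns had nearly equal distributions, with medians of 34.8 to 35.8. The genomic DNA columns were not masked and had medians of 65 and 73 over the probe sets tested, and how they were scaled to each other is not given in the sources used here. They were therefore centred on the median of their difference.

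Of 22810 probe sets, 1371 had no RNA value, among them all 64 control probe sets, and 21439 were tested. The platform annotation gave 1 gene symbol for 12605 of these, several for 454 and none for 8380. Genes were named only from probe sets with 1 symbol. No genome was used, so that no coordinates are given. The annotation did not name ADH1, PDC1, SUS1, SUS4, HB1, HRE1, LBD41 or PCO1, and their values are not reported here. Detection calls were not used here. Between 25.6% and 26.7% of the values of an array lay below an intensity of 16, and changes among such dim values are poorly determined.

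One model of 6 group means was fitted to the 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), which left 12 residual degrees of freedom. There were 10 comparisons: the submergence response of each genotype, the 3 differences between these responses, the species difference in air and under water, and the F1 hybrid against the mean of the parental log2 means (the mid-parent) in air and under water. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. Errors of log2 differences are the moderated standard errors of the fit (SE). The labels call the 3 arrays of a group biological replicates. The number of arrays limits the precision of each value.

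Gene lists were tested by counting called members and with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members, and again with an estimated correlation. A locus with several probe sets was represented by the brightest. The groups, the tests, the rule for named genes, 23 gene lists and all alternatives except the one on linear means were fixed before the data were examined. Of the 458 loci on these lists 92 were measured, and 6 lists had at least 5 measured loci. A further 12 lists of gene families were drawn up from the annotation's names before any value was tested.

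Genes were named by rule, among probe sets with 1 gene symbol and an adjusted p under 0.05. Groups that did not overlap were also required, except for response differences and hybrid comparisons. In hybrid comparisons every F1 hybrid array had instead to lie on the same side of the mid-parent. The 5 largest rises and 5 largest falls of each submergence response were taken, and the 4 largest in each direction of every other comparison. For the species and hybrid comparisons the genomic DNA values had also to differ by under 0.5 on the log2 scale. For each list the up to 4 members with the smallest p were added.

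The fits were tested on simulated data with 200 changed probe sets among 21439. For the response of R. amphibia, 28.4% of seeded changes of 0.5 on the log2 scale, 95.5% of those of 1 and 100% of those of 2 were recovered, with 7 false calls. For the response difference between the species the shares were 2.99%, 58.2% and 95.5%, with 4 false calls, and for the F1 hybrid against the mid-parent in air 52.2%, 95.5% and 100%, with 10 false calls. Of 50 seeded and 50 unchanged lists simulated for the response of R. amphibia, camera called 50 and 2. Noise was drawn independently for each probe set, so that these simulations do not show how calls behave among correlated genes. Only 200 probe sets were changed, against 4092 called in the real response of R. amphibia. The adjusted p depends on how many probe sets change, so that the recovered shares need not hold for the real comparisons. Alternatives covered the scaling between arrays, a floor of 16, dim and cross-hybridising probe sets, a fold threshold, the variance model, the genomic DNA difference, the replicate number as a block, the arrays in the fit, each array left out in turn, and a mid-parent of linear means, which was added after the data had been seen.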

Results

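The submergence response of roots was compared between Rorippa amphibia, Rorippa sylvestris, both relatives of Arabidopsis thaliana, and their F1 hybrid. Each of the 6 groups (3 genotypes, air or 24 h of complete submergence) had 3 arrays, each of a pool of 3 plants. Within groups the arrays correlated at 0.985 to 0.992 across probe sets, and the median SD between replicates was 0.134 to 0.156 on the log2 scale. The first principal component (34.8% of the variance) separated submerged from air-grown roots. The second (28.8%) separated the species, with the F1 hybrid between them in each treatment. Within each treatment R. sylvestris also lay below R. amphibia on the first component. On the third component (6.37%) every F1 hybrid array lay below every parental array.

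**Figure D1:**
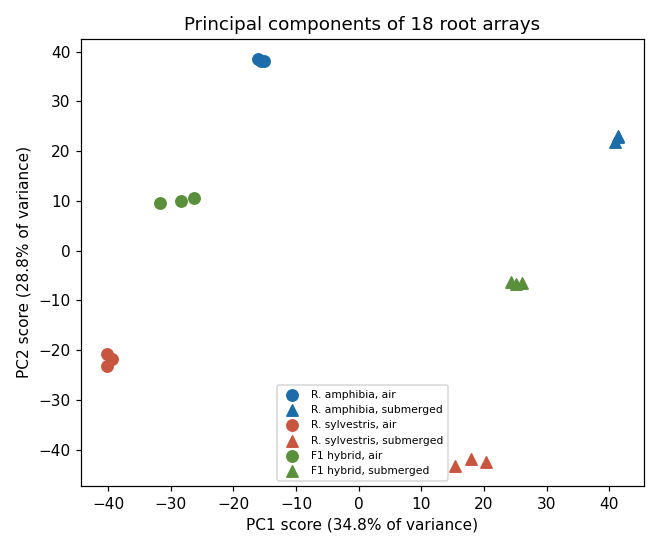
Scores of the 18 RNA arrays on the first principal component (horizontal axis, 34.8% of the variance) and the second (vertical axis, 28.8%), in units of log2 intensity; each point is 1 array, colours show the genotype and shapes the treatment. All submerged arrays lie to the right of all air arrays, and the F1 hybrid lies between the parents on the second component.

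Some of the largest rises under water among the genes named occurred in all genotypes. AT3G29970, a B12D-like gene, rose by 4.95 in R. amphibia, 5.70 in R. sylvestris and 3.91 in the F1 hybrid on the log2 scale (SE 0.231, n = 3 arrays per group), and AT1G28100 rose by 4.55, 4.89 and 4.36 (SE 0.212). PDF1.4, of the plant defensin family, rose by 3.66, 5.96 and 5.42 (SE 0.123). The chitinase family gene AT2G43610 rose by 4.08, 4.67 and 3.16 (SE 0.249), and AT5G10210 by 3.79, 3.72 and 3.28 (SE 0.198). The highest group mean of AT5G10210 was an intensity of 105, so that its rises started from dim values below log2 4. AT1G19530 rose by 3.38 in the F1 hybrid and by 0.69 and 0.93 in R. amphibia and R. sylvestris (SE 0.191). With a highest group mean of 150, it also started below log2 4 in the F1 hybrid. The deepest fall in each genotype among the genes named was that of AT5G04120, which changed by -4.68, -4.70 and -5.51 (SE 0.3). It ended at submerged means of 3.1, 3.44 and 3.32, below log2 4, where intensities are dim.

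The sugar transporter gene SWEET14 and the pectate lyase family gene AT1G11920 were among the deepest falls of the genes named. SWEET14 changed by -2.86 in R. amphibia, -2.87 in R. sylvestris and -2.50 in the F1 hybrid (SE 0.202). AT1G11920 changed by -3.53, -2.80 and -2.50 (SE 0.258). With a highest group mean of 169, it ended below log2 4 in R. amphibia, where intensities are dim. The SKU5-like gene sks15 changed by -2.62 in R. amphibia and -3.00 in the F1 hybrid (SE 0.26), and AT5G02540 by -2.58 in R. amphibia (SE 0.368). AT4G33550 changed by -2.79 in R. sylvestris and -3.23 in the F1 hybrid (SE 0.134), and AT5G60520 by -2.69 and -2.66 (SE 0.143). In limma's test 4092 probe sets passed in R. amphibia (1902 higher, 2190 lower), 4427 in R. sylvestris (2063 and 2364) and 4045 in the F1 hybrid (1881 and 2164), of 21439 tested. Of these, 851, 929 and 725 changed at least 2-fold.

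Genes of the low-oxygen response rose together in every genotype. Of 25 measured members, 17 rose in R. amphibia, 19 in R. sylvestris and 16 in the F1 hybrid, and none fell; adjusted over the list alone, 19 rose in each and 1 fell in the F1 hybrid. AT5G10040 rose by 4.1, 4.69 and 3.50 (SE 0.198), and PDC2, a pyruvate decarboxylase of ethanolic fermentation, by 1.70, 0.81 and 0.74 (SE 0.129). The highest group mean of AT5G10040 was an intensity of 380, so that in R. sylvestris its rise started from dim values below log2 4. AT4G27450 rose by 4.25 in R. sylvestris and 2.90 in the F1 hybrid (SE 0.241), and AT4G10270 by 2.73 and 1.76 (SE 0.167). Both genes also rose in R. amphibia. In limma's camera test the adjusted p of the list was 2.11e-15, 8.98e-14 and 2.14e-13, and 0.00043, 0.00074 and 0.000844 with an estimated correlation.

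**Figure D2:**
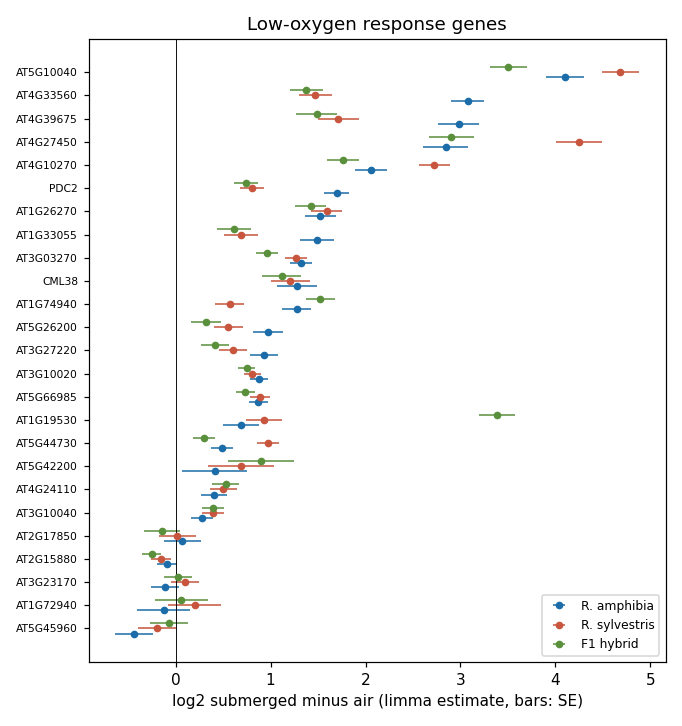
Log2 change under water (horizontal axis, submerged minus air, limma estimate with SE bars, 3 arrays per group) of the 25 measured low-oxygen genes (vertical axis) in the 3 genotypes, shown by colour. AT1G19530 stands at 3.38 in the F1 hybrid and at 0.69 and 0.93 in the parents.

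Glycolytic genes moved in both directions. Of 10 measured, 7 rose and 2 fell in R. amphibia, 4 and 2 in R. sylvestris, and 6 and 2 in the F1 hybrid; adjusted over the list alone the counts were 7 and 2, 6 and 2, and 6 and 2. The cytosolic phosphoglucose isomerase gene AT5G42740 rose by 1.29, 1.66 and 1.1 (SE 0.097). Subunits of pyrophosphate-dependent phosphofructokinase moved apart: AT1G76550 rose by 2.52, 2.1 and 1.68 (SE 0.133), while AT1G20950 changed by -1.76, -1.17 and -1.40 (SE 0.104) and AT1G12000 by -1.75, -1.51 and -1.67 (SE 0.106). The list passed limma's camera in R. amphibia (adjusted p = 0.00747) and R. sylvestris (0.0236) and not in the F1 hybrid (0.0906). These were adjusted p = 0.0645, 0.17 and 0.281 with an estimated correlation. Of 8 measured genes of the TCA cycle, 1 rose and 2 fell in R. amphibia, 1 and 5 in R. sylvestris and 1 and 3 in the F1 hybrid, the same counts as adjusted over the list alone, and the list did not pass (adjusted p = 0.37, 0.0913 and 0.185). AT2G20420, for a subunit of succinyl-CoA ligase, changed by -0.39, -0.48 and -0.55 (SE 0.087).

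Genes for loosening and remodelling of the cell wall fell under water. Of 14 measured expansins and xyloglucan hydrolases, 8 fell and 1 rose in R. amphibia, 10 fell in R. sylvestris and 11 in the F1 hybrid, the same counts as adjusted over the list alone. XTH16 changed by -2.16, -1.94 and -2.02 (SE 0.216), XTH19 by -2.05, -1.87 and -2.11 (SE 0.208) and EXPB1 by -1.10, -1.51 and -1.28 (SE 0.124). The highest group means of XTH16 and XTH19 were intensities of 70.2 and 58.3, so that in R. amphibia both ended at dim values below log2 4. Both measured members of a list of 6 root hair genes are expansins of this list and moved with it: EXPA7 changed by -1.19, -1.36 and -1.42 (SE 0.171), and EXPA18 by -0.82 in R. sylvestris and -0.95 in the F1 hybrid (SE 0.144), with -0.17 in R. amphibia that did not pass. Adjusted over the list alone, 1, 2 and 2 root hair genes fell, the same counts. The expansin and xyloglucan hydrolase list's adjusted p in limma's camera was 4.73e-05, 1.95e-07 and 3.98e-10, and 0.0362, 0.00773 and 0.00223 with an estimated correlation. Of 22 genes of the trichome birefringence-like family, whose characterised members acetylate wall polysaccharides, 7, 8 and 8 fell and none rose (adjusted p = 0.00823, 0.000856 and 0.00326, and 0.0413, 0.00773 and 0.0245 with an estimated correlation). TBL39 changed by -0.87, -1.32 and -1.45 (SE 0.121). Of 7 tubulins 4, 4 and 3 fell, with TUB1 at -1.01, -1.17 and -1.03 (SE 0.118) and TUB7 at -0.88, -0.87 and -0.93 (SE 0.116). The tubulin calls (adjusted p = 0.00747, 0.0154 and 0.00326) were lost at adjusted p = 0.0645, 0.14 and 0.068 with an estimated correlation.

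Antioxidant and translation genes fell in part. Of 5 measured genes of reactive oxygen metabolism, 3 fell in R. amphibia, 1 in R. sylvestris and 1 in the F1 hybrid, and none rose; adjusted over the list alone the falls were the same and 1 rose in R. sylvestris. GSTU25, a tau class glutathione transferase, changed by -1.50 in R. amphibia (SE 0.184), with values of 0.52 and -0.14 that did not pass in R. sylvestris and the F1 hybrid. The list passed limma's camera in R. amphibia (adjusted p = 0.00995), with adjusted p = 0.0596 with an estimated correlation. Of 11 tau glutathione transferases 4 fell and 1 rose in R. amphibia, and 3 fell and none rose in each of R. sylvestris and the F1 hybrid, with GSTU28 at -1.18, -0.92 and -0.65 (SE 0.158) and GSTU22 at -0.76, -0.94 and -0.85 (SE 0.146). The family passed camera in R. amphibia (adjusted p = 0.00823, and adjusted p = 0.0774 with an estimated correlation) and not in R. sylvestris (0.178) or the F1 hybrid (0.0906, and 0.0308 without F1 hybrid submerged replicate 2). Of 107 cytosolic ribosomal protein genes 24 fell and 1 rose in R. amphibia, 9 and 1 in R. sylvestris and 17 and 1 in the F1 hybrid. AT2G40010 changed by -0.97, -1.05 and -1.07 (SE 0.168) and AT1G18540 by -0.72, -0.58 and -0.62 (SE 0.128). The ribosomal list passed camera in R. amphibia (adjusted p = 0.00019) and the F1 hybrid (0.00326), with adjusted p = 0.267 and 0.463 with an estimated correlation. Its call in the F1 hybrid was lost without F1 hybrid air replicate 1 (adjusted p = 0.0528) or submerged replicate 3 (0.0532).

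A minority of green-tissue markers and organelle-encoded genes rose under water. Of 5 photosynthesis genes listed as markers of shoot material, 2 rose in R. amphibia and 1 in each of R. sylvestris and the F1 hybrid, with LHCB4.1, a light-harvesting protein gene, at 1.69, 0.77 and 1.1 (SE 0.148). Adjusted over the list alone, 2 rose in R. amphibia. The list passed limma's camera in R. amphibia alone (adjusted p = 0.0466), which became adjusted p = 0.243 with an estimated correlation. That call was lost without R. amphibia air replicate 3 (0.0641), R. amphibia submerged replicate 2 (0.1), F1 hybrid air replicate 1 (0.05) or F1 hybrid air replicate 2 (0.055). Of 54 chloroplast-encoded genes 3, 6 and 6 rose and 1, 0 and 0 fell, with psbJ at 0.61 in R. sylvestris and 0.64 in the F1 hybrid (SE 0.122) and rbcL at -0.95 in R. amphibia (SE 0.159). That list passed camera in R. sylvestris (adjusted p = 0.000972) and the F1 hybrid (0.00326), with adjusted p = 0.482 and 0.494 with an estimated correlation. It was lost without R. sylvestris submerged replicate 3 (0.0611) and without F1 hybrid air replicate 2 (0.0846) or submerged replicate 2 (0.0834). Of 16 mitochondrion-encoded genes 1, 5 and 3 rose, with nad5 of respiratory complex I at 1.00 in R. sylvestris and 0.93 in the F1 hybrid (SE 0.193), and that list passed in both (adjusted p = 0.000972 and 0.00326), with adjusted p = 0.17 and 0.224 with an estimated correlation.

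The responses of the genotypes were shared to a large extent. Across probe sets the log2 changes of R. amphibia and R. sylvestris correlated at a Pearson r of 0.736 (Spearman 0.581), those of R. amphibia and the F1 hybrid at 0.777 (0.602), and those of R. sylvestris and the F1 hybrid at 0.796 (0.639). Probe sets are not independent replicates, and no array was shared between these comparisons. Between the species, 1145 probe sets rose in both against 183 for independent lists, 1407 fell in both against 241, and 27 went in opposite directions. In all 3 genotypes 939 rose and 1183 fell, of 6726 called in at least 1.

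Among the genes named, the response difference between the species was largest in AT3G19030, AT4G23960 and the defensin gene PDF1.4. AT3G19030 differed by 2.52 (SE 0.242), with means of 6.61 in air and 6.61 under water in R. amphibia and 7.41 and 9.92 in R. sylvestris. PDF1.4 rose more in R. sylvestris, by 2.30 (SE 0.174), and GSTU25 differed by 2.03 (SE 0.26) and AT5G59940 by 1.97 (SE 0.305). In the other direction, AT4G23960 differed by -2.34 (SE 0.345), the peroxidase gene AT5G64120 by -2.00 (SE 0.464), AT4G13160 by -1.97 (SE 0.258) and the glycosyltransferase gene AT2G22590 by -1.88 (SE 0.169). AT5G64120 did not pass without any R. amphibia air array, R. amphibia submerged replicate 1 or 3, R. sylvestris air replicate 1 or 2, or R. sylvestris submerged replicate 1 or 3 (adjusted p = 0.055 to 0.0915). Of 25 low-oxygen genes 1 responded more in R. sylvestris and 3 less, or 3 and 5 adjusted over the list alone, and limma's camera did not call the list (adjusted p = 0.565). PDC2 rose less (difference -0.89, SE 0.183, adjusted p = 0.0142), as did AT4G33560 (-1.60, SE 0.251, adjusted p = 0.002). PDC2 was already higher in R. sylvestris in air (0.665, SE 0.129, limma adjusted p = 0.000995). Under water its species difference did not pass (-0.227, SE 0.129, limma adjusted p = 0.242). AT4G27450 rose more (1.41, SE 0.341, adjusted p = 0.0415), a call that held without R. amphibia air replicate 3, R. sylvestris air replicate 2 or F1 hybrid air replicate 1 or 3 and was lost without any of the other 14 arrays (adjusted p = 0.0504 to 0.111). In air AT4G27450 was lower in R. sylvestris (-1.855, SE 0.241, limma adjusted p = 1.75e-05), so that its larger rise started from a lower level. The expansin gene EXPA4, already lower in R. sylvestris in air (-3.36), fell less there (1.11, SE 0.209, adjusted p = 0.00778). In limma's test of the difference itself, 384 probe sets passed, 184 with a higher and 200 with a lower response in R. sylvestris, and 199 differed at least 2-fold.

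**Figure D3:**
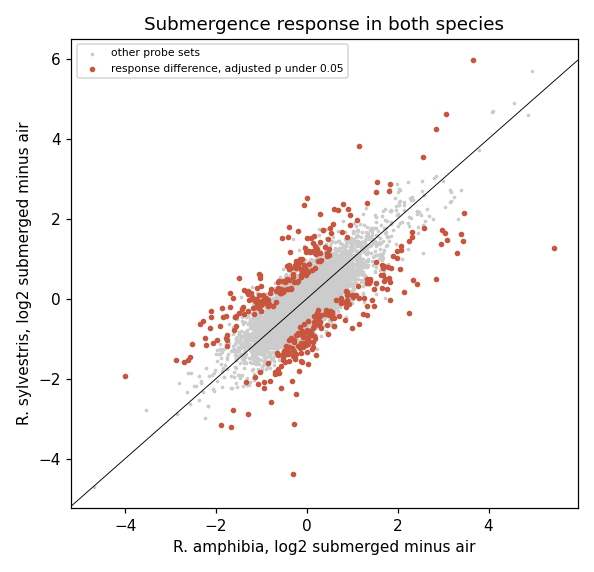
Log2 change under water (submerged minus air) of each of the 21439 probe sets in R. amphibia (horizontal axis) and R. sylvestris (vertical axis), as limma estimates from 3 arrays per group. Coloured points are the 384 whose response differed between the species at an adjusted p under 0.05, and the line marks equal responses.

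The F1 hybrid departed most from both parents, among the genes named, in AT1G19530. The hybrid's response of this gene was 2.69 above that of R. amphibia and 2.45 above that of R. sylvestris (SE 0.27). Against R. amphibia, AT1G29270 differed by 2.43 (SE 0.262) and PDF1.4 by 1.76 (SE 0.174), while AT2G39040, a class III peroxidase gene, differed by -1.87 (SE 0.247), AT4G33560 by -1.70 (SE 0.251) and AT4G33550 by -1.61 (SE 0.19). Against R. sylvestris, the thionin gene THI2.1 differed by 1.89 (SE 0.293), AT1G21520 by 1.35 (SE 0.224) and EXPA4 by -1.48 (SE 0.209). In limma's test 62 probe sets differed from R. amphibia (27 higher, 35 lower) and 89 from R. sylvestris (48 and 41). The count of 62 was 41 without R. amphibia air replicate 2, 34 without air replicate 3, 40 without R. amphibia submerged replicate 1 and 37 without submerged replicate 3. It was 32 and 40 without F1 hybrid air replicates 1 and 2, and 30 and 31 without F1 hybrid submerged replicates 1 and 2. The count of 89 was 45 and 41 without R. sylvestris air replicates 1 and 3, 47 without R. sylvestris submerged replicate 3, 44 without F1 hybrid air replicate 2, and 55 and 43 without F1 hybrid submerged replicates 1 and 2. With only the arrays of the groups compared in the fit the counts were 33 and 50.

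Another 2 genes named by the same rule against R. amphibia and 4 against R. sylvestris lost their call in some fits with 1 array left out. AT2G43550 differed from R. amphibia by 1.58 (SE 0.303) and did not pass without any R. amphibia submerged or F1 hybrid submerged array, R. amphibia air replicate 2 or 3, or F1 hybrid air replicate 1 or 2 (limma adjusted p = 0.0503 to 0.0955). AT3G60470 differed by -1.86 (SE 0.338) and did not pass without R. amphibia air replicate 3, R. amphibia submerged replicate 2 or 3, F1 hybrid air replicate 1 or 2, or F1 hybrid submerged replicate 1 or 2 (0.0511 to 0.0723). From R. sylvestris, GPDHC1 differed by -2.03 (SE 0.41), the most negative value among the genes named, and did not pass without any R. sylvestris array, F1 hybrid air replicate 2 or 3, or F1 hybrid submerged replicate 2 or 3 (0.0517 to 0.101). THIC differed by 1.39 (SE 0.288) and did not pass without any F1 hybrid submerged array, F1 hybrid air replicate 2 or 3, R. sylvestris air replicate 2 or 3, R. sylvestris submerged replicate 3, R. amphibia air replicate 3, or R. amphibia submerged replicate 1 or 3 (0.052 to 0.104). AT3G29970 differed by -1.79 (SE 0.327) and did not pass without R. sylvestris air replicate 1, R. sylvestris submerged replicate 1 or 3, or F1 hybrid submerged replicate 3 (0.0516 to 0.06), and the chitinase family gene AT1G56680 by -1.67 (SE 0.294) and did not without R. sylvestris air replicate 1 or 3 or F1 hybrid air replicate 2 (0.0508 to 0.0531).

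Species differences were as widespread as the response to water. In air AT2G14160 was higher in R. sylvestris by 5.35 (SE 0.112), AT1G12990 by 4.23 (SE 0.22), the glutaredoxin gene AT5G20500 by 3.78 (SE 0.24) and the dirigent family gene AT2G39430 by 3.46 (SE 0.133). AT2G18740 differed by -4.41 (SE 0.158), AT3G44180 by -4.18 (SE 0.149), AT3G22290 by -4.01 (SE 0.207) and AT3G50180 by -3.92 (SE 0.124). Under water AT2G14160 (4.97, SE 0.112), GSTU25 (3.59, SE 0.184), AT1G12990 (3.59, SE 0.22) and AT3G58760 (3.58, SE 0.202) were higher in R. sylvestris, and AT3G22290 (-4.35, SE 0.207), AT3G59350 (-4.33, SE 0.198), AT2G18740 (-4.08, SE 0.158) and ARV2 (-3.80, SE 0.198) were lower. Several of these lay below log2 4 in the lower species, such as AT2G14160 at 3.02 in R. amphibia in air and AT3G44180 at 3.01 in R. sylvestris.

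Among listed genes EXPA4 was lower in R. sylvestris by -3.36 in air and -2.25 under water (SE 0.148), as was the low-oxygen gene AT1G74940 by -1.28 and -1.99 (SE 0.153). The acetylation-related gene TBL34 was higher by 2.27 and 2.02 (SE 0.133) and the ribosomal protein gene AT3G56340 by 3.36 and 3.51 (SE 0.133). Of 14 expansins and xyloglucan hydrolases 5 were lower in R. sylvestris and 2 higher in air, and 5 lower and none higher under water, the same counts as adjusted over the list alone. EXPA15 was higher in air by 0.86 (SE 0.191), as was EXPA18 by 0.42 (SE 0.144, adjusted p = 0.044), which did not pass without R. amphibia air replicate 2 or 3, R. amphibia submerged replicate 1 or 2, R. sylvestris air replicate 1 or 2, F1 hybrid air replicate 1 or F1 hybrid submerged replicate 1 (adjusted p = 0.0507 to 0.176). The list passed limma's camera under water (adjusted p = 0.00992, and adjusted p = 0.466 with an estimated correlation) and not in air (0.63). Of 107 ribosomal protein genes 12 were higher and 5 lower in air (adjusted p = 0.63), and 30 and 4 under water (adjusted p = 0.00992, and adjusted p = 0.95 with an estimated correlation). The ribosomal call was lost without R. amphibia submerged replicate 1 (0.0595). In limma's test 4442 probe sets differed in air (2242 higher in R. sylvestris, 2200 lower) and 4947 under water (2518 and 2429). Of these 2857 passed in both treatments with the same sign, against 513 for independent lists, and 38 with opposite signs. The species differences of both treatments correlated at 0.777 across probe sets, which are not independent replicates.

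Sequence divergence from the Arabidopsis probes was compared through the genomic DNA arrays, with 1 array per species and hence no test. The genomic DNA values were not masked, unlike the RNA values, so that both may rest on different probes of a probe set. The difference between the genomic DNA arrays had an SD of 0.117 on the log2 scale, and 16 probe sets differed by at least 0.5. It correlated with the species difference in RNA across probe sets at a Spearman rho of 0.062 in air and 0.060 under water. Of the probe sets called, 55.2% in air and 54.2% under water had a genomic DNA difference of the same sign.

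The F1 hybrid lay away from the mid-parent in a small share of probe sets. AT2G14160 stood above it by 2.60 in air and 2.88 under water (SE 0.097), with hybrid means of 8.30 and 8.64 beside 8.37 and 8.24 in R. sylvestris and 3.02 and 3.28 in R. amphibia, the latter dim values below log2 4. Against a mid-parent of linear means AT2G14160 stood above by 0.89 and 1.35. BGLU25, of the beta-glucosidase family, differed by -1.99 and -2.11 (SE 0.11), with hybrid means of 5.86 and 6.04 below those of R. amphibia (7.62 and 7.72) and R. sylvestris (8.09 and 8.58). In air the peroxidase gene AT2G39040 (1.63, SE 0.151), AT2G13890 (1.42, SE 0.097) and the aspartyl-tRNA synthetase gene AT4G26870 (1.34, SE 0.105) were higher, the last 2 by 0.85 and 0.79 against linear means, and AT1G65510 (-2.01, SE 0.291), AT5G09480 (-1.46, SE 0.153) and AT1G60770 (-1.39, SE 0.217) were lower. Under water AT1G19530 (2.55, SE 0.166), the thiamine synthesis gene THIC (2.18, SE 0.176) and AT1G29270 (1.91, SE 0.16) were higher, and AT4G33550 (-2.18, SE 0.116), AT3G60470 (-1.86, SE 0.207) and AT5G61670 (-1.85, SE 0.122) were lower.

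At the preset correlation, tubulins and low-oxygen genes lay above the mid-parent as groups, and chloroplast-encoded and glycolytic genes below it. Of 7 tubulins 3 were higher in air and 2 under water and none lower, with TUB6 at 0.54 and 0.73 (SE 0.104); limma's camera gave adjusted p = 0.000378 and 0.00373, and adjusted p = 0.0532 and 0.128 with an estimated correlation. Of 25 low-oxygen genes 3 were higher in air and none lower, or 5 and none adjusted over the list alone (adjusted p = 0.00964, and adjusted p = 0.239 with an estimated correlation), a call lost without F1 hybrid air replicate 1 (0.256). Of 54 chloroplast-encoded genes 2 were higher and 5 lower in air (adjusted p = 0.00178, and adjusted p = 0.769 with an estimated correlation), lost without F1 hybrid air replicate 2 (0.283). Under water 1 was higher and 3 lower (adjusted p = 0.0224, and adjusted p = 0.852 with an estimated correlation), lost without R. amphibia submerged replicate 2 (0.199), R. sylvestris submerged replicate 2 (0.0549) or 3 (0.23), or F1 hybrid submerged replicate 1 (0.287) or 3 (0.149). Of 10 glycolytic genes 2 were lower under water and none higher, also adjusted over the list alone (adjusted p = 0.0224, and adjusted p = 0.277 with an estimated correlation), lost without R. amphibia submerged replicate 2 (0.0928) or F1 hybrid submerged replicate 3 (0.149).

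In limma's test 612 probe sets differed from the mid-parent in air (327 higher, 285 lower) and 743 under water (424 and 319). With a mid-parent of linear means the counts were 486 (170 and 316) and 593 (226 and 367), so that the share of higher calls was 35.0% and 38.1% instead of 53.4% and 57.1%. The count in air was 400 and 338 without F1 hybrid air replicates 1 and 2, and that under water 398, 383 and 350 without F1 hybrid submerged replicates 1, 2 and 3. With only the arrays of the groups compared in the fit the counts were 366 and 490. Among all 21439 probe sets every hybrid array lay above every parental array for 364 in air and 463 under water, and below for 488 and 605, together 3.97% and 4.98%. Arrays that could be exchanged freely would give 2.38%. The parents differed from each other in many probe sets, so that this share is not an exact baseline. Of the probe sets called in air and under water, 101 and 162 lay above every parental array and 162 and 201 below. Of the calls 258 were shared by both treatments with the same sign, against 11 for independent lists, and 2 had opposite signs.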

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

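The exchanges with genotype means removed and the mid-parent of linear means, also by direction of the calls, were tests chosen only after the result was seen.

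The results below met a test of the difference between 2 genotypes in their response to water. Between the species 384 probe sets differed in limma's test (n = 3 arrays per group). The largest differences among the genes named were those of AT3G19030 (2.52), PDF1.4 (2.30), GSTU25 (2.03), AT5G59940 (1.97), AT4G23960 (-2.34), AT4G13160 (-1.97), AT2G22590 (-1.88) and the peroxidase gene AT5G64120 (-2.00). All but the last passed in every fit with 1 array left out. AT5G64120 (adjusted p = 0.0324) did not pass without R. amphibia air replicate 1 (0.055), 2 (0.0698) or 3 (0.0779), R. amphibia submerged replicate 1 (0.0915) or 3 (0.0907), R. sylvestris air replicate 1 (0.0573) or 2 (0.0909), or R. sylvestris submerged replicate 1 (0.0665) or 3 (0.0888).

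Between the F1 hybrid and R. amphibia 62 probe sets differed in response. The named ones were AT1G19530 (2.69), AT1G29270 (2.43), PDF1.4 (1.76), AT2G43550 (1.58), AT2G39040 (-1.87), AT3G60470 (-1.86), AT4G33560 (-1.70) and AT4G33550 (-1.61). AT2G43550 (limma adjusted p = 0.0304) did not pass without R. amphibia air replicate 2 (0.0756) or 3 (0.0955), R. amphibia submerged replicate 1 (0.0665), 2 (0.0603) or 3 (0.0816), F1 hybrid air replicate 1 (0.0503) or 2 (0.0807), or F1 hybrid submerged replicate 1 (0.0774), 2 (0.0585) or 3 (0.0785). AT3G60470 (0.0217) did not pass without R. amphibia air replicate 3 (0.0723), R. amphibia submerged replicate 2 (0.0545) or 3 (0.0713), F1 hybrid air replicate 1 (0.0541) or 2 (0.0597), or F1 hybrid submerged replicate 1 (0.0645) or 2 (0.0511).

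Between the F1 hybrid and R. sylvestris 89 probe sets differed in response. The named ones were AT1G19530 (2.45), THI2.1 (1.89), THIC (1.39), AT1G21520 (1.35), GPDHC1 of glycerol-3-phosphate metabolism (-2.03), AT3G29970 (-1.79), the chitinase family gene AT1G56680 (-1.67) and EXPA4 (-1.48). THIC (limma adjusted p = 0.0412) did not pass without R. amphibia air replicate 3 (0.056), R. amphibia submerged replicate 1 (0.0555) or 3 (0.052), R. sylvestris air replicate 2 (0.104) or 3 (0.0874), R. sylvestris submerged replicate 3 (0.095), F1 hybrid air replicate 2 (0.104) or 3 (0.06), or F1 hybrid submerged replicate 1 (0.104), 2 (0.0728) or 3 (0.0891). GPDHC1 (0.0355) did not pass without R. sylvestris air replicate 1 (0.0517), 2 (0.0752) or 3 (0.0963), R. sylvestris submerged replicate 1 (0.0522), 2 (0.067) or 3 (0.0888), F1 hybrid air replicate 2 (0.101) or 3 (0.0763), or F1 hybrid submerged replicate 2 (0.0631) or 3 (0.0993). AT3G29970 (0.0195) did not pass without R. sylvestris air replicate 1 (0.06), R. sylvestris submerged replicate 1 (0.0538) or 3 (0.0546), or F1 hybrid submerged replicate 3 (0.0516). AT1G56680 (0.0172) did not pass without R. sylvestris air replicate 1 (0.0517) or 3 (0.0531) or F1 hybrid air replicate 2 (0.0508).

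The response of 5 gene lists differed between genotypes in limma's camera at the preset correlation and not with an estimated one. Against R. amphibia, the F1 hybrid had a mean difference of -0.165 over the low-oxygen genes (adjusted p = 0.0278; adjusted p = 0.162 with an estimated correlation), with 1 of 25 higher and 3 lower, or 1 and 5 adjusted over the list alone. It was not called without R. amphibia air replicate 3 (0.0588), F1 hybrid air replicate 1 (0.0781) or F1 hybrid submerged replicate 3 (0.0516). The mean for glycolysis was -0.233 (adjusted p = 0.0278; adjusted p = 0.162 with an estimated correlation), with none of 10 genes passing, or 2 lower adjusted over the list alone, and the call was lost without R. amphibia air replicate 3 (0.0588), R. amphibia submerged replicate 2 (0.0681), F1 hybrid air replicate 1 (0.0781) or F1 hybrid submerged replicate 3 (0.109). For expansins and xyloglucan hydrolases it was -0.284 (adjusted p = 0.00929; adjusted p = 0.162 with an estimated correlation), with none of 14 passing, or 2 lower adjusted over the list alone, and it was lost without F1 hybrid air replicate 1 (0.0767). For reactive oxygen genes it was 0.424 (adjusted p = 0.0301; adjusted p = 0.162 with an estimated correlation), with 1 of 5 higher, also adjusted over the list alone, and it was lost without R. amphibia air replicate 3 (0.0588), R. amphibia submerged replicate 3 (0.0551), F1 hybrid air replicate 1 (0.0781) or F1 hybrid submerged replicate 2 (0.187). Between the species the ribosomal proteins differed by 0.122 (adjusted p = 0.00637; adjusted p = 0.668 with an estimated correlation) with no gene passing, and the call was lost without R. amphibia submerged replicate 1 (0.106).

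Whether the response differences could arise from any grouping of the arrays was tested with 100 exchanges of genotype within treatments, the real one included. As many calls came from 11 exchanges for the species (384 calls, highest other 2392), 13 for the F1 hybrid against R. amphibia (62, 3305) and 12 for the F1 hybrid against R. sylvestris (89, 760), so that this test does not exclude chance. Counts several times the real one point to a structure of the samples, since an exchange that mixes the genotypes unequally in air and under water turns part of the genotype difference into a response difference. With each genotype's mean removed first, 1 of 100 exchanges, the real one, gave as many calls in each comparison. The highest others were 3, 2 and 2. The means were removed by the true genotype labels, which keeps the real response difference whole and shrinks it in the exchanges. That favours the real grouping, so this version does not exclude chance either. A biological difference between the genotypes remains an open hypothesis, found and tested on the same arrays.

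For the submergence responses, 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave as many calls (4092, 4427 and 4045, highest others 1, 2 and 0). The same holds for the species differences, with 1 of 10 splits (4442 in air and 4947 under water, highest others 0 and 0). Unequal hybridisation of the species' sequences to the Arabidopsis probes could enter the species differences. Among the 146 calls of at least 4-fold in air, 84 (57.5%, 95% interval 49.1 to 65.7%) had a genomic DNA difference of the same sign, and among the 179 under water 115 (64.2%, 56.8 to 71.3%). These intervals treat probe sets as independent and hold no spread between arrays, as each species had 1 genomic DNA array. Genomic DNA differences were small beside those in RNA, with a median of 0.027 and 0.065 in the direction of these calls against 2.56 and 2.51, and 6 calls of any size in each treatment had one of at least 0.5. Size decides little, because the genomic DNA arrays spanned a narrow range, with medians of 65 and 73 for probe sets tested and 51 and 60 for those without an RNA value. The upper end of the interval was not under 60% and neither share reached 75%, the bounds set for the calls in air, so that hybridisation stays open as the cause of most large calls, as does a difference in expression between the clones.

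For the F1 hybrid against the mid-parent, 4 of 100 splits of the 9 arrays gave as many calls in air (612, highest other 2981). Under water it was also 4 of 100 (743, highest other 3311). These shares lie close to 0.05 and come from a draw of splits rather than from all of them. Most splits also mix the species within a group, which widens the residual spread and lowers their counts. The test therefore does not exclude chance. The splits with more calls left 3 arrays of a group together in 1 place and at least 2 in every other, so that their counts point to the structure of the groups. Averaging the parents on the log scale could by itself place a hybrid at the linear mean above the mid-parent. With linear means 71.4% of the calls in air and 70.9% of those under water were called again, but of the higher calls, which alone this could produce, 52% (95% interval 46.4 to 57.5%) and 53.3% (48.4 to 58.1%), against 93.7% and 94.4% of the lower ones. The scale therefore stays open as the cause of most higher calls and does not account for the lower ones. The intervals treat probe sets as independent replicates, which they are not. The share of higher calls went from 53.4% to 35.0% and from 57.1% to 38.1%. Whether more genes lie above or below the mid-parent therefore depends on the scale.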

How the results depend on the processing

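All 10 counts of calls stayed within 1.5 times their value under median centring, quantile normalization, the replicate block, a floor of 16, moderation with trend and robust variance, and without dim or cross-hybridising probe sets. With at least a 2-fold change required, which by construction lowers a count, the submergence responses had 851 (R. amphibia), 929 (R. sylvestris) and 725 (F1 hybrid) calls, the response differences 199 (species), 41 (F1 hybrid against R. amphibia) and 58 (F1 hybrid against R. sylvestris), the species differences 954 in air and 1044 under water, and the F1 hybrid against the mid-parent 71 and 75. With only the arrays of the groups compared, and so fewer residual degrees of freedom, the F1 response differences had 33 and 50 calls and the mid-parent comparisons 366 and 490. Leaving out 1 array gave 30 to 68 and 41 to 93 calls for the F1 response differences and 338 to 637 and 350 to 811 for the mid-parent comparisons. The correlation of the species' responses ranged from 0.704 to 0.736 and that of RNA with genomic DNA differences from 0.058 to 0.065, against 0.07 without dim probe sets, for which the cause was not tested. With an estimated correlation 9 of the 23 list calls of the submergence responses and none of the 13 of the other comparisons were kept. No named gene or list reversed. A floor of 16, which bears on dim values, ended 40 calls of named genes and added 13 among 1048 gene results, and the replicate block ended 17 and added 5. Replicate numbers were not treated as pairs: residuals of arrays with the same number correlated at -0.086 to 0.151 (median -0.005). Among arrays of other groups, 10 of the 18 arrays correlated best with one of their own number. A weak link between arrays of the same number therefore stays open. Correcting for genomic DNA gave 4857 calls in air and 5454 under water for the species.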

Other observations

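The tests of the F1 hybrid's response size and of the submergence score were chosen only after the result was seen.

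Class III peroxidases moved in both directions under water. Of 52 measured, 4 rose and 6 fell in R. amphibia, 8 and 8 in R. sylvestris and 4 and 7 in the F1 hybrid, and limma's camera did not call the family (adjusted p = 0.474, 0.795 and 0.41). AT4G11290 rose by 1.53, 1.38 and 1.19 (SE 0.111, n = 3 arrays per group), while AT3G49960 changed by -1.03, -1.12 and -1.14 (SE 0.122). Of 13 SWEET sugar transporters 1, 1 and 2 rose and 2 fell in each genotype, and SWEET3 rose by 1.22, 1.41 and 1.2 (SE 0.231) as SWEET14 fell. Of 20 beta-glucosidases 3, 2 and 2 rose and 3, 4 and 4 fell, with BGLU15 at -0.96, -1.09 and -1.10 (SE 0.093) and PYK10, an abundant root beta-glucosidase, at 0.83 in R. sylvestris and 0.64 in the F1 hybrid (SE 0.138).

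Of 47 UDP-glycosyltransferases 2, 2 and 4 rose and 3, 3 and 4 fell, with UGT72E2 at -0.96, -0.91 and -0.77 (SE 0.115). Of 9 histones 2, 1 and 2 fell, with HTB4 at -0.60, -0.84 and -0.59 (SE 0.105). Of 8 autophagy genes of the ATG8 family 0, 1 and 0 rose and 0, 1 and 1 fell, with ATG8H at -0.57 in R. sylvestris and -0.62 in the F1 hybrid (SE 0.099). ATG8F rose by 0.28 in R. sylvestris (SE 0.093, limma adjusted p = 0.038) and did not pass without any R. sylvestris air array or R. sylvestris submerged replicate 1 or 2 (0.0516 to 0.161). IVD, of branched-chain amino acid breakdown, rose by 1.32, 1.64 and 1.42 (SE 0.125) and ARL by 0.68, 0.62 and 0.76 (SE 0.129). The reference genes AT4G34270 and AT2G28390 did not pass limma's test in any genotype, with values from -0.10 to 0.11.

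The F1 hybrid had the fewest submergence calls, also of at least 2-fold (725 against 851 in R. amphibia and 929 in R. sylvestris). A candidate explanation was a smaller response than that of its parents. Because genes chosen in a parent overstate that parent's response, the F1 hybrid was compared with the parent not used for the choice. Over the 4427 probe sets called in R. sylvestris the mean response was 0.589 in the F1 hybrid and 0.574 in R. amphibia (exact permutation p = 0.655 over 400 regroupings), and over the 4092 called in R. amphibia it was 0.599 and 0.619 in R. sylvestris (exact p = 0.41). A smaller response of the F1 hybrid was not found in this way. Across probe sets the F1 hybrid's changes correlated with those of R. amphibia and R. sylvestris at a Pearson r of 0.777 and 0.796, above the 0.736 between the species. Probe sets called in a parent may therefore favour the F1 hybrid over the other parent, so that a smaller response is not excluded.

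Roots of R. sylvestris in air might have lain nearer to the submerged state than those of R. amphibia. The score of an array was the mean log2 value of the probe sets that rose in the F1 hybrid minus that of those that fell. It was -0.627 (SD 0.025) in R. sylvestris and -0.477 (SD 0.013) in R. amphibia in air, a difference of -0.149 in the opposite direction (n = 3 arrays per group). With 3 against 3 arrays the smallest exact p is 0.1. Submerged, the scores were 0.741 in R. sylvestris and 0.803 in R. amphibia, again lower in R. sylvestris. The score can also hold species differences in level or hybridisation that do not depend on water. It therefore cannot decide which species in air lay nearer to the submerged state.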
